A study of Mus musculus with 24 samples.

How the data were processed

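Bone marrow-derived macrophages (BMDM) of 3 mouse genotypes were profiled by RNA sequencing: wild type (WT), a Hdac9 knockout (KO), and a deletion of a cis-regulatory element that the labels abbreviate as dCIS. Each genotype was studied untreated and after 6 hours with 100 ng/ml lipopolysaccharide (LPS), a bacterial ligand of the receptor TLR4. Each of the 6 groups held 4 libraries, 24 in all, and the replicate numbers 1 to 4 come from the labels. Nothing in the labels says that the libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical.

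Libraries were made from 200 ng of total RNA captured on oligo-dT beads and read for 60 nucleotides in paired-end mode, per the labels' protocols. The deposited table holds whole-number counts per mouse gene, made by the authors, for all 24 libraries. Per the submitters' processing notes the tools were STAR and edgeR and the genome build was mm39; the versions, the counting program, the strand setting and the annotation release are not given in the sources used here. Genes that overlap on opposite strands, and close paralogs, can therefore not be separated beyond what the authors' counting did. The table lists 56941 gene IDs, of which 51948 (91.2%) matched a symbol in the gene name table used here; IDs without a symbol held 0.562% to 3.44% of the counts of a library. Only names, and the order of genes along the chromosomes in the GRCm38 assembly for the question which genes neighbour each other, were taken from outside the deposited table. No coordinates are given, because GRCm38 is not the build of the counts.

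Total counts per library ranged from 14636058 to 19181707. No pair of libraries of a group agreed within sampling noise, by a chi-square test of their counts. Levels in CPM were computed here on library sizes scaled by TMM. Intervals from counts would cover counting error only, since PCR reads without molecular identifiers are not independent molecules, so spread is given as the SD over the 4 libraries of a group.

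Genes were kept by the filter of edgeR that takes the groups into account (a minimum count of 10 and a minimum total of 15), which left 14757 genes. All 24 libraries entered 1 quasi-likelihood fit (edgeR 4.0.16, R 4.3.3) with a mean per group and no further covariate, so that all comparisons share 1 estimate of the spread. Each comparison was tested by the quasi-likelihood F test, and adjusted p-values are Benjamini-Hochberg values over all tested genes from edgeR unless another tool is named. A gene was called at an adjusted p under 0.05. Log2 fold changes are given with their standard error (SE), and group levels as mean CPM with the SD of 4 libraries. The tests are 2-sided. The comparisons are LPS against untreated within each genotype, the 3 pairs of genotypes at each treatment, and the differences of the LPS response of KO and of dCIS from that of WT. For Hdac9, the cell cycle score and other values tested alone, an exact permutation test of 4 against 4 libraries was used, whose smallest 2-sided p is 0.0286.

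Gene lists for pathways, for the histone deacetylases, for sex genes and for markers of other cell types were fixed with the design; 26 of 28 had at least 3 tested members. They were tested with camera (limma 3.58.1) on voom values at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 26 lists. With the correlation estimated from the data, camera called 0 lists in each of the 11 comparisons, and its adjusted p is given beside each list. The test fry asks whether the genes of a list move one way, without comparing them with other genes. Members of a list were also counted with p-values adjusted over the list alone.

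The genes named follow a rule. They are Hdac9, the up to 10 largest rises and falls per comparison among called genes with at least 5 CPM in the higher group and no overlap between the groups, up to 4 called members per list with the smallest p, called neighbours of Hdac9, and in each genotype comparison Il1b, Nlrp3, Tnf, Il6, Abca1 and Abcg1. Gene models named only by a number, a clone or a pseudogene suffix are counted but not named. Some genes that the rule selects are not reported here. Genes outside the rule are said to have been chosen after their values were seen. Groups, comparisons, lists, the naming rule and the alternatives were fixed before the data were examined, except where an alternative is said to be chosen after seeing the data.

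The alternatives were size factors computed by the median-of-ratios method (RLE), no filter and a stricter filter (at least 1 CPM in at least 4 libraries), the replicate number as a block over all groups or within each genotype, a fit of the compared groups alone, DESeq2 1.42.0, and fits without each library in turn. Fits without dCIS LPS libraries 3 and 4 together, without dCIS LPS libraries 1 and 2 together, and without both KO libraries numbered 2 were chosen after seeing the data. The numbers were checked for pairing by correlating the deviations of the libraries from their group means. Untreated and LPS libraries of the same number correlated at 0.113 to 0.15 in WT and at 0.155 to 0.296 in KO, above the limit of 0.1 for all 4 pairs, so the numbers pair the libraries across treatments in these genotypes; in dCIS the range was 0.0396 to 0.339. Between genotypes, all 4 pairs exceeded the limit only for KO and dCIS untreated (0.114 to 0.359). The pairing is a property of the values, since the labels do not say what a number stands for.

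The simulations of unchanged groups for shared WT libraries drew the WT libraries too, a choice made after seeing the data, because WT libraries held at their own mean carry no shared chance. They drew genes and libraries independently, and so leave out the correlation by number of untreated KO and dCIS libraries.

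The scripts were tested on simulated counts drawn from the means and library sizes of these data. For KO vs WT untreated, 32.2% of genes changed 1.5-fold, 59.5% of those changed 2-fold and 86.6% of those changed 4-fold were recovered, with 8 of 129 calls false (6.2%) over 14757 genes run. For the difference of the LPS response of KO from WT the shares were 17.7%, 48.6% and 73.5%, with 4 of 99 calls false (4.04%) over 14757 genes run. A planted list of 20 genes raised 1.5-fold was called, and 0 of the other 25 lists at the same adjusted p of camera. The simulated genes were drawn independently, so this does not test the preset correlation on real lists whose genes move together.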

Results

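RNA was sequenced from bone marrow-derived macrophages of 3 mouse genotypes, untreated and 6 hours after 100 ng/ml LPS, with 4 libraries in each of the 6 groups. The genotypes are wild type (WT), a knockout of Hdac9 (KO), which encodes a class IIa histone deacetylase, and a deletion of a cis-regulatory element (dCIS). The title of the series ties the element to Hdac9 expression and to inflammation that depends on the inflammasome, the complex that activates caspase-1. Total counts per library lay between 15750606 and 16128430 in untreated WT, 15716390 and 19181707 in untreated KO, and 15600199 and 16902065 in untreated dCIS. After LPS they lay between 16328738 and 16712666 in WT, 14636058 and 16570668 in KO, and 14813435 and 16651501 in dCIS. Libraries 3 and 4 of dCIS after LPS had 17628 and 15997 genes with at least 1 count, against at least 20458 in each of the other 22 libraries. Levels are CPM, counts relative to the scaled library size, as the mean ± SD of 4 libraries. For each called gene named, the libraries of the compared groups did not overlap, except where an overlap is stated.

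Hdac9 RNA was nearly lost in KO and was not lower in dCIS than in WT. Untreated WT macrophages had 11.2 ± 1.46 CPM, KO 1.04 ± 0.218 CPM and dCIS 15.6 ± 2.23 CPM. After LPS the levels were 12.3 ± 2.83, 0.302 ± 0.155 and 14.7 ± 5.26 CPM. Hdac9 therefore fell by 3.43 on the log2 scale in untreated KO against WT (SE 0.246, adjusted p 1.38e-09) and by 5.32 after LPS (SE 0.335, adjusted p 1.37e-10), where KO libraries had 1 to 5 counts. In untreated dCIS each of the 4 libraries lay above the highest WT library, 13.0 CPM at the lowest against 12.4 CPM, with a log2 fold change of 0.47 (SE 0.197). That difference did not pass edgeR over all genes (adjusted p 1) and had an exact 2-sided permutation p of 0.0286, the smallest the design allows, which is 0.0429 after Benjamini-Hochberg adjustment over 9 Hdac9 comparisons. After LPS the log2 fold change of dCIS against WT was 0.25 (SE 0.204, adjusted p 0.647, exact p 0.629). It depended on single libraries: dCIS libraries 3 and 4 were at 9.89 and 10.96 CPM against 16.5 and 21.2 CPM in 1 and 2, and the value was 0.61 without 3 and 4 (adjusted p 0.361) and 0.01 without library 2. LPS itself left Hdac9 at a log2 fold change of 0.13 in WT (SE 0.202, adjusted p 0.591) and -0.09 in dCIS (SE 0.199, adjusted p 0.703). The sign changed without WT LPS library 2 (-0.04) and without dCIS LPS library 3 (0.06) or 4 (0.02). In KO it fell by 1.76 after LPS (SE 0.43, adjusted p 0.000924), but the difference of that response from WT did not pass the test (log2 -1.89, SE 0.479, adjusted p 1).

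**Figure D1:**
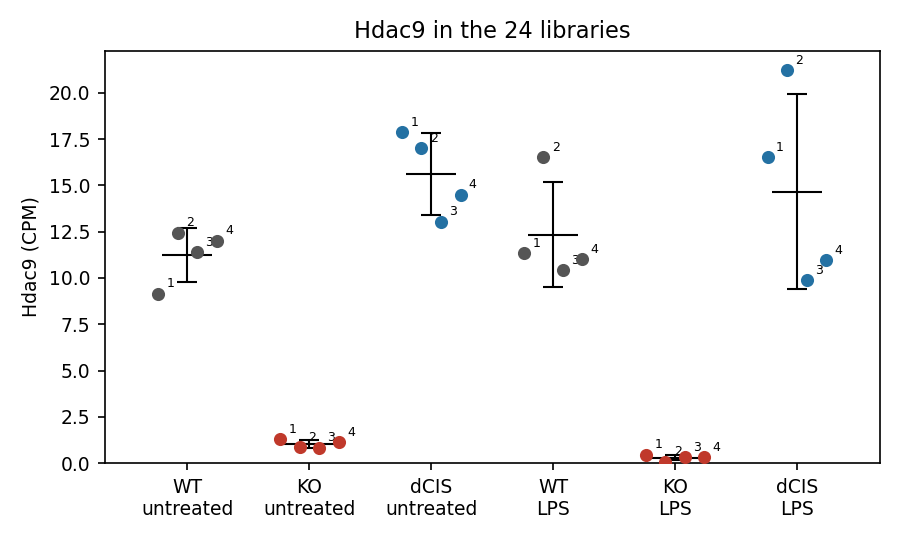
Hdac9 level in CPM (vertical axis) in each of the 24 libraries, by genotype and treatment; numbers mark the replicate, bars the mean and error bars 1 SD of 4 libraries. KO libraries lie near 0 and the 4 untreated dCIS libraries above the 4 untreated WT libraries.

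The first comparison asks how WT macrophages respond to LPS. They switched on inducible nitric oxide synthase, cytokines and chemokines from close to nothing. Nos2 rose from 0.692 ± 0.775 to 2000 ± 203 CPM, Il6 from 0.306 ± 0.246 to 601 ± 175 CPM, and Il12b, a subunit shared by interleukins 12 and 23, from 0.153 ± 0.0578 to 321 ± 88.6 CPM. The chemokine gene Ccl5 rose from 7.07 ± 2.6 to 6159 ± 279 CPM and Cxcl10, an interferon-induced chemokine, from 8.58 ± 3.59 to 8826 ± 207 CPM. Lipg, which encodes endothelial lipase, rose 1240-fold (log2 10.28, SE 0.252). Angpt1 and Ptx3 had no counts in any untreated WT library and were at least 267-fold and at least 284-fold higher after LPS, against a floor of 3 counts over the group. Among the genes that fell most, Cebpa, a transcription factor of myeloid cells, went from 65.1 ± 10.5 to 2.33 ± 0.521 CPM, the cannabinoid receptor gene Cnr2 from 10.8 ± 0.526 to 0.12 ± 0.0831 CPM, and the lipid desaturase gene Scd2 from 426 ± 69.9 to 22.2 ± 4.49 CPM. Rasgrp3 was at 7 ± 1.58 CPM untreated and 0.0388 ± 0.0777 CPM after LPS, which is 2 counts over 4 libraries. The log2 fold change of Rasgrp3 was -7.21, and -9.90 without WT LPS library 2, and that of Nos2 11.47, and 12.39 without untreated WT library 1. edgeR called 9055 genes, 4484 higher and 4571 lower, and 14 of 26 gene lists passed camera at the preset correlation.

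Whole pathways rose together in WT. All 17 measured inflammatory cytokines and chemokines rose, with a median log2 fold change of 6.15 (camera adjusted p 5.37e-11; 0.0871 with an estimated correlation). So did all 28 genes of the type I interferon response (median 5.58, adjusted p 3.01e-25; 0.0871 with an estimated correlation), such as Cmpk2 from 29.1 ± 1.72 to 6386 ± 208 CPM and Gbp2 from 21.1 ± 1.1 to 3611 ± 188 CPM. All 18 genes of NF-kB feedback rose (median 2.81, adjusted p 2.24e-13; 0.0871 with an estimated correlation), among them Traf1 and Nfkb2, with log2 fold changes of 4.95 and 3.21. All 12 genes of MHC class I presentation rose (median 2.42, adjusted p 5.65e-10; 0.0871 with an estimated correlation), including Tap1, a transporter of peptides, and Nlrc5, a transcriptional activator of the class I genes. Of 20 measured genes of the inflammasome and IL-1 family, 15 rose and 4 fell (median 1.47, adjusted p 0.000254; 0.131 with an estimated correlation). Il18 rose from 6.70 ± 0.876 to 181 ± 13 CPM, and Casp1 from 87.0 ± 5.27 to 510 ± 11.6 CPM. The DNA sensor gene Aim2 rose from 25.9 ± 1.45 to 157 ± 2.67 CPM.

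Smaller rises in WT covered 12 of 15 genes of TLR4 receptor and signalling (3 fell; adjusted p 0.00248; 0.194 with an estimated correlation), 9 of 18 of glycolysis (1 fell; 0.00248; 0.448), 9 of 10 of complement (0.00564; 0.194), 7 of 9 of MHC class II and co-stimulation (8 adjusted over the list alone; 0.00632; 0.101) and 7 of 12 of immediate early and heat shock (1 fell; 0.0118; 0.164), each pair of values in that order. The adaptor Myd88 rose from 75.6 ± 1.08 to 482 ± 5.86 CPM and the glycolytic regulator Pfkfb3 from 45.1 ± 6.09 to 484 ± 8.98 CPM. C3 rose from 90.0 ± 19 to 1621 ± 299 CPM and the co-stimulatory receptor Cd40 from 14.0 ± 1.53 to 1596 ± 57.3 CPM. All 4 measured genes of the fibroblast and endothelial list rose (adjusted p 0.00632; 0.096 with an estimated correlation), with Kdr, a receptor of vascular endothelial growth factor, at 38.0 ± 5.54 CPM and Pdgfrb, a growth factor receptor, at 8.35 ± 1.81 CPM after LPS. Of 23 cell cycle genes 20 fell and 2 rose (median -2.10, adjusted p 0.000134; 0.51 with an estimated correlation). The replicative helicase genes Mcm2 and Mcm7 fell by 3.35 and 2.82 on the log2 scale. Of 17 histone deacetylases 11 fell and 3 rose, 12 and 3 adjusted over the list alone (median -0.82, adjusted p 0.0311; 0.174 with an estimated correlation). The class IIa members Hdac5 and Hdac4 went from 74.4 ± 9.53 to 7.33 ± 0.707 CPM and from 12.6 ± 0.555 to 4.56 ± 0.799 CPM, while Hdac1, a class I member, rose from 35.5 ± 1.58 to 129 ± 5.24 CPM. In cholesterol synthesis 9 of 19 genes fell and 2 rose (median -0.39, adjusted p 0.032; 0.69 with an estimated correlation), with Dhcr7 from 56.4 ± 8.67 to 7.84 ± 1.57 CPM. The list of MEF2 factors and class IIa HDAC-linked genes did not pass (4 of 13 rose and 6 fell, adjusted p 0.296), although Mef2c and Mef2d, whose products are bound by class IIa deacetylases, fell by 2.11 and 1.41.

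The other lists did not pass camera in WT, and their called members were 4 higher and 3 lower of 12 for alternative activation, 6 and 6 of 16 for cholesterol efflux and lipid uptake, 3 and 3 of 11 for the NRF2 oxidative stress response, 6 and 3 of 13 for matrix remodelling and 8 and 3 of 13 for macrophage identity. Of 11 mitochondrially encoded genes edgeR and DESeq2 called 0, with 0 at an unadjusted p under 0.05. Of 3 neutrophil genes 1 rose, of 3 dendritic cell genes 2 rose, of 3 lymphocyte genes 1 rose and 2 fell, of 5 osteoclast genes 1 rose and 2 fell, and of 4 sex genes 1 rose and 1 fell. Mmp13, a collagenase gene of the matrix list, rose from 24.7 ± 3.45 to 2079 ± 444 CPM.

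The same comparison within KO and within dCIS asks whether the response to LPS holds without Hdac9 or without the element. It did for the leading genes. Il6 rose from 0.192 ± 0.229 to 610 ± 84 CPM in KO and from 0.119 ± 0.103 to 376 ± 74.1 CPM in dCIS. In the same order Nos2 rose from 0.93 ± 1.44 to 2221 ± 358 CPM and from 0.0841 ± 0.0618 to 2744 ± 228 CPM, and Ccl5 from 5.13 ± 2.12 to 5748 ± 444 CPM and from 4.19 ± 1.38 to 5299 ± 379 CPM. Cnr2 and Lpar5, which encode receptors for lipids, fell by 6.26 and 6.85 on the log2 scale in KO (SE 0.384 and 0.525), and E2f2, a transcription factor of the cell cycle, fell by 5.76 in dCIS (SE 0.367). Brca2, a gene of DNA repair, was at 6.46 ± 2.44 CPM in untreated dCIS and at 0.0614 ± 0.0786 CPM after LPS (log2 -6.59; -7.60 without dCIS LPS library 2). Without untreated KO library 2 the log2 fold change in KO went from 11.48 to 12.75 for Il6 and from 11.1 to 13.32 for Nos2. edgeR called 9085 genes in KO (4558 higher, 4527 lower) and 9547 in dCIS (4626 higher, 4921 lower). In all 3 genotypes 7538 genes were called, of which 3823 rose and 3711 fell in each. Across genes, which are not independent replicates, log2 fold changes in KO and WT had r = 0.966, and those in dCIS and WT r = 0.947.

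Inflammatory gene lists rose in KO and in dCIS too. All 17 inflammatory cytokines and chemokines, all 28 genes of the type I interferon response, all 18 of NF-kB feedback and all 12 of MHC class I presentation rose in both. In the inflammasome and IL-1 family 15 of 20 rose and 4 fell in KO (median 1.39, camera adjusted p 0.000708; 0.142 with an estimated correlation), and 14 rose and 3 fell in dCIS (median 1.37, adjusted p 0.000113; 0.118 with an estimated correlation). Cell cycle genes fell in 18 of 23 cases in KO (3 rose; adjusted p 0.000351, 0.576 with an estimated correlation) and in 20 of 23 in dCIS (1 rose; adjusted p 5.13e-06, 0.406 with an estimated correlation). With the preset correlation 13 of 26 lists passed in KO and 12 in dCIS. With the estimated correlation 0 passed in either.

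**Figure D2:**
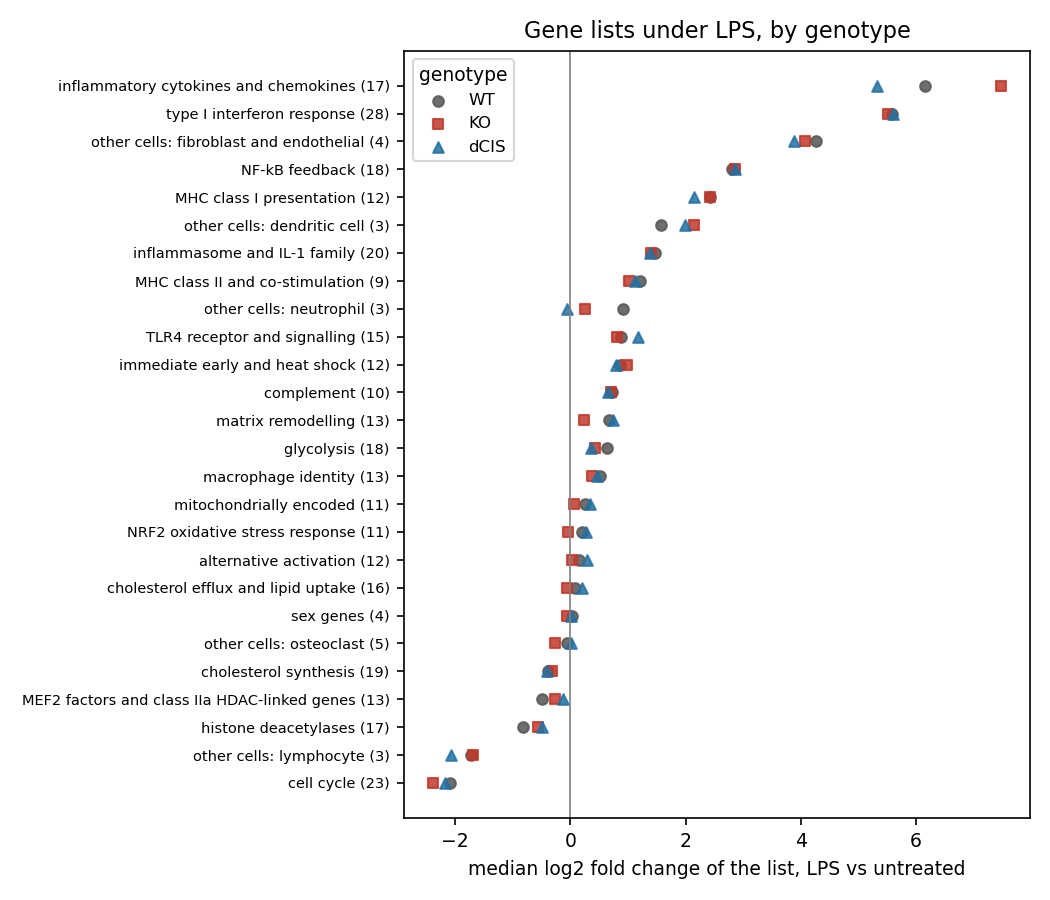
Median log2 fold change of LPS against untreated (horizontal axis) for each gene list in WT, KO and dCIS, with the number of measured genes in brackets. Cytokine and interferon genes lie highest and cell cycle genes lowest, and the cytokine medians are spread most, with KO highest and dCIS lowest.

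Whether the response to LPS differed between genotypes was tested gene by gene. In KO 3 genes passed. Nol10, which encodes a nucleolar protein, rose more than in WT (difference 1.31 on the log2 scale, SE 0.173, adjusted p 0.000731). Adi1, an enzyme of methionine salvage, fell less (difference 1.47, SE 0.248, adjusted p 0.0163), and Rnf144a, an E3 ubiquitin ligase, differed by -3.26. The call of Adi1 was lost without any 1 of 7 libraries, namely untreated WT 4 (adjusted p 0.0546), untreated KO 1 (0.0604) and 4 (0.0579), WT after LPS 1 (0.0791), 2 (0.0688) and 3 (0.0882), and KO after LPS 2 (0.0607), and in a fit of the compared groups alone (0.0869). The named inflammatory genes did not pass: the differences were 0.20 for Il1b, 0.35 for Nlrp3, 0.26 for Tnf and 0.58 for Il6, each at adjusted p 1. Of all tested genes 258 (1.75%) were at an unadjusted p under 0.05, fewer than chance alone would give. The main fit leaves out the pairing by number in WT and KO. With the number as a block within each genotype, 83 named gene results on LPS over the 3 genotypes kept their call and direction, and 1 gained a call. Not passing still does not show an equal response. The type I interferon response as a list had a median difference of -0.20 in KO (camera adjusted p 0.0088; 0.977 with an estimated correlation), with 0 of 28 members called by edgeR or DESeq2 and 0 at an unadjusted p under 0.05. In dCIS edgeR called 0 genes, with 1159 at an unadjusted p under 0.05 and 1 called by DESeq2. Leaving out untreated dCIS library 2 gave 3 calls. The smallest adjusted p, 0.0737, was that of Mier3, a transcriptional co-regulator. Il1b and Nlrp3 differed by -0.25 and 0.27 (adjusted p 0.935 and 0.786). MHC class I presentation had a median difference of -0.27 (camera adjusted p 0.0115) and the list of MEF2 factors and class IIa HDAC-linked genes 0.30 (0.0192). Each was at 0.999 with an estimated correlation and at 1 by fry, and without dCIS LPS libraries 3 and 4 the MEF2 list did not pass (0.0537).

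**Figure D3:**
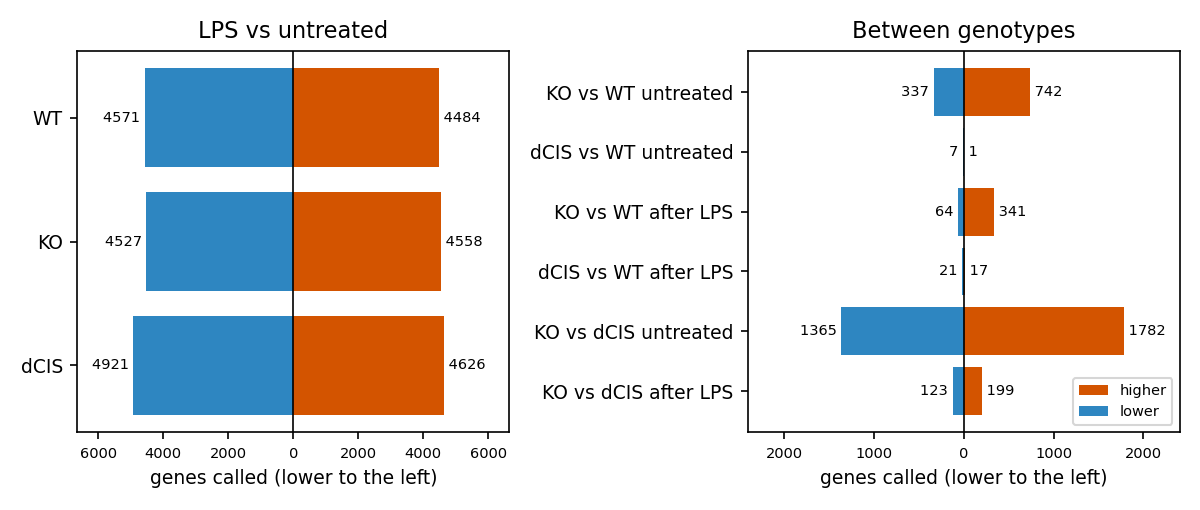
Number of genes called by edgeR at an adjusted p under 0.05 (horizontal axis), higher to the right and lower to the left, for LPS against untreated in each genotype (left) and between genotypes at each treatment (right, on its own scale). LPS called 9055 genes in WT, while dCIS against WT called 8 untreated and 38 after LPS.

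Untreated KO and WT macrophages differed in several genes by more than 2-fold besides Hdac9. Odc1, the rate-limiting enzyme of polyamine synthesis, was at 30.3 ± 4.82 CPM in KO against 77.2 ± 9.94 CPM in WT (log2 -1.35, SE 0.156, adjusted p 5.6e-06). Akr1c12, an aldo-keto reductase, was at 1.73 ± 0.238 against 6.31 ± 0.718 CPM (log2 -1.86, SE 0.198, adjusted p 1.63e-06). Acp1, a phosphotyrosine phosphatase, and Ero1lb, an oxidase of the endoplasmic reticulum, fell by 1.07 and 1.28. Odc1 and Acp1 lie on the chromosome of Hdac9, so their change may stem from the mouse line and not from the loss of Hdac9. The same may hold for genes on other chromosomes, such as Akr1c12, Ero1lb, Wdfy1, Steap3 and Adam19. In a test chosen after seeing the data, the changed genes there also lay near each other, with 13 such loci against a 95th percentile of 8 in random sets. Higher in KO were Wdfy1, an endosomal protein, at 34.1 ± 2.67 against 10.5 ± 1.74 CPM (log2 1.70, SE 0.134, adjusted p 5.83e-09), and Steap3, a ferrireductase, at 93.6 ± 12.3 against 36.2 ± 3.53 CPM (log2 1.37, SE 0.144, adjusted p 1.53e-06). The metalloprotease gene Adam19 was at 6.82 ± 4.92 against 1.08 ± 0.323 CPM (log2 2.66, SE 0.362; 2.01 without KO library 2, which had 14.2 CPM against at most 4.70 in the others). Mmp9, a gelatinase, was at 87.2 ± 44.4 against 23.9 ± 6.73 CPM with overlapping libraries (log2 1.86, SE 0.377, adjusted p 0.00841).

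The main inflammasome and cytokine genes passed no test between untreated KO and WT. Nlrp3 was at 60.0 ± 6.45 and 60.0 ± 14.5 CPM (log2 0.00, SE 0.164, adjusted p 0.999), Il1b at 3.04 ± 1.95 and 2.99 ± 1.77 CPM, and Tnf had a log2 fold change of -0.18 (SE 0.197, adjusted p 0.607). Of 20 genes of the inflammasome and IL-1 family 2 rose, Naip2 and Naip6, which encode sensors of bacterial proteins (camera adjusted p 0.26), with log2 fold changes of 0.40 and 0.77 (adjusted p 0.0484 and 0.0295). The call of Naip2 was lost without any 1 of the 8 libraries (adjusted p 0.0666 to 0.172), and that of Naip6 without WT library 1 (0.0612), 2 (0.112) or 3 (0.0863) or KO library 1 (0.0734), 2 (0.0532) or 3 (0.0709). Of 28 genes of the type I interferon response 3 rose in KO, 8 adjusted over the list alone, with 12 at an unadjusted p under 0.05 and 11 called by DESeq2 (median 0.29, camera adjusted p 0.022; 0.831 with an estimated correlation). The 3, Cmpk2, Ddx58 and Mx2, lost their calls without KO library 1 (adjusted p 0.0785, 0.0891 and 0.127) or 3 (0.122, 0.112 and 0.16) or WT library 2 (0.11, 0.12 and 0.142) or 3 (0.0863, 0.0989 and 0.146). Cmpk2 and Ddx58 also lost them without WT library 1 (0.0571 and 0.0841), and Mx2 in a fit of the 8 libraries alone (0.117). The interferon list did not pass with the replicate number as a block (0.0526) or by fry (0.353). Of 23 cell cycle genes edgeR called 0, with 5 at an unadjusted p under 0.05 and 2 called by DESeq2 (median -0.28, camera adjusted p 0.022; 0.831 with an estimated correlation). Among all tested genes 25.2% were at such a p in this comparison, close to the share of the cell cycle list. The complement gene C3 was at 164 ± 43.5 against 90.0 ± 19 CPM (adjusted p 0.0203). Its call was lost without WT library 2 (adjusted p 0.0982) or 3 (0.0688) or KO library 3 (0.0592) or 4 (0.0561). Abca1, a cholesterol exporter, was at 293 ± 122 against 158 ± 29.4 CPM (adjusted p 0.0479), and its call was lost without any 1 of the 7 libraries other than WT 4 (adjusted p 0.0525 to 0.19).

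In total 1079 genes were called in untreated KO against WT, 742 higher and 337 lower. With RLE scaling they were 1129 and 292. The number depended on single libraries: it was 476 without WT 1, 90 without WT 2, 126 without WT 3, 209 without KO 1, 233 without KO 3 and 493 without KO 4. It rose to 1973 with the replicate number as a block, to 2351 in a fit of the 8 libraries alone, to 2164 with DESeq2 (1631 higher, 533 lower) and to 1770 without dCIS LPS libraries 3 and 4, a setting chosen after seeing the data. The composition of the libraries differed too: ribosomal protein genes took 1.96 to 2.12% of counts in untreated KO and 2.51 to 2.87% in WT, and 1.27 to 1.38% and 1.57 to 1.88% after LPS. Mitochondrial genes took 1.83 to 2.38% and 1.23 to 1.89% untreated, where the ranges overlap.

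After LPS, Odc1, Steap3, Wdfy1 and Adam19 again differed between KO and WT. Odc1 was at 38.2 ± 6.4 in KO against 134 ± 12.1 CPM in WT (log2 -1.81, SE 0.159, adjusted p 3.66e-08) and Steap3 at 39.0 ± 7.35 against 9.31 ± 1.47 CPM (log2 2.06, SE 0.16, adjusted p 4.22e-09). Wdfy1 was at 76.9 ± 7.5 against 27.0 ± 4.01 CPM (log2 1.51, SE 0.131) and Adam19 at 12.3 ± 2.1 against 2.01 ± 0.489 CPM (log2 2.61, SE 0.359). Adi1 was at 24.8 ± 5.46 against 4.58 ± 0.85 CPM (log2 2.43, SE 0.191, adjusted p 4.3e-09). Ccdc39, known from motile cilia, was at 18.5 ± 1.02 against 1.40 ± 0.171 CPM and Gpr141b, an orphan receptor gene, at 8.42 ± 1.79 against 0.2 ± 0.191 CPM. Cd200, the ligand of an inhibitory receptor of myeloid cells, was at 5.69 ± 1.83 against 24.7 ± 4.67 CPM (log2 -2.13, SE 0.3, adjusted p 0.000128), and Glrp1 at 0.0456 ± 0.0527 against 6.05 ± 1 CPM, from 2 counts in KO.

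The main inflammasome and cytokine genes passed no test after LPS in KO. These are RNA levels, and the activity of the inflammasome was not measured, so they do not answer whether it changed. Il1b was at 1059 ± 115 in KO and 921 ± 335 CPM in WT (log2 0.20, SE 0.319, adjusted p 0.769) and Nlrp3 at 802 ± 67.5 and 632 ± 116 CPM (log2 0.35, SE 0.161, adjusted p 0.217). Tnf was at 1869 ± 336 and 1772 ± 325 CPM and Il6 at 610 ± 84 and 601 ± 175 CPM (log2 0.02, SE 0.22, adjusted p 0.968). Abca1 had a log2 fold change of 0.71 (SE 0.279, adjusted p 0.143). Of 20 genes of the inflammasome and IL-1 family and of 17 inflammatory cytokines and chemokines edgeR called 0 each, with 4 and 3 at an unadjusted p under 0.05 and 0 and 1 called by DESeq2. Of all 14757 tested genes 21.2% were at such a p, so these counts do not set the lists apart. Camera called 0 of 26 lists and so did fry, while camera called 2 with the replicate number as a block. C3 was at 2805 ± 669 against 1621 ± 299 CPM (adjusted p 0.0367). That call was lost without WT library 1 (adjusted p 0.0534), 2 (0.128) or 3 (0.193) or KO library 1 (0.104), 2 (0.11) or 4 (0.054). edgeR called 405 genes, 341 higher and 64 lower. Without single libraries the number was 202 (WT 1), 100 (WT 2), 68 (WT 3), 91 (KO 1), 215 (KO 2) and 109 (KO 3). It was 1038 without a filter, 1058 with the block, 1995 in a fit of the 8 libraries alone, 1093 with DESeq2 and 872 without dCIS LPS libraries 3 and 4. In both treatments 267 genes were called, all 267 in the same direction.

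**Figure D4:**
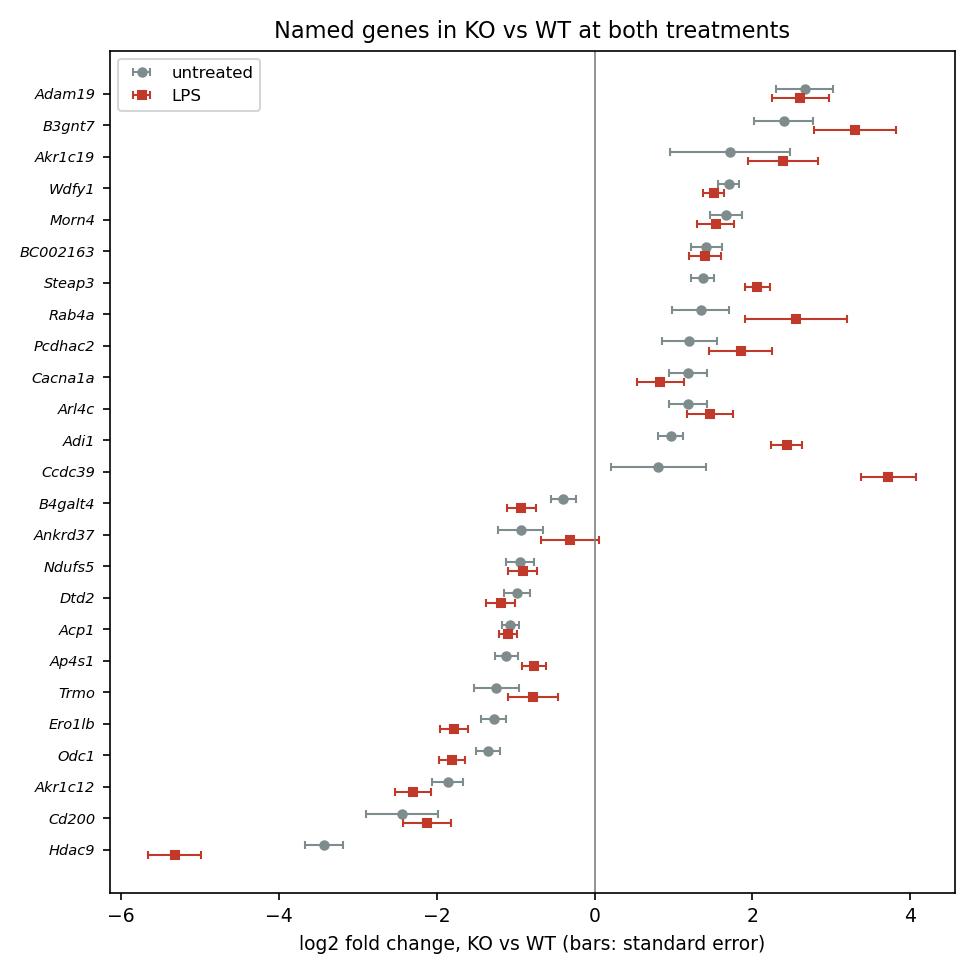
Log2 fold change of KO against WT (horizontal axis, error bars 1 SE) for named genes, untreated and after LPS, 4 libraries per group. Odc1 and Akr1c12 lie below 0 and Wdfy1, Steap3 and Adam19 above 0 at both treatments, and Hdac9 lies lowest.

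Untreated dCIS macrophages had less RNA of Hpn and Sbno1 than WT. Hpn, which encodes the serine protease hepsin, was at 0.97 ± 0.146 against 6.33 ± 0.609 CPM (log2 -2.70, SE 0.379, adjusted p 0.00062). Sbno1, a transcriptional regulator, fell by 0.73 (SE 0.113, adjusted p 0.00228), and Etv1, a transcription factor of the ETS family, was at 2.90 ± 0.993 against 7.99 ± 1.54 CPM (adjusted p 0.0112). The call of Etv1 was lost without WT library 3 (adjusted p 0.0795) or 4 (0.0686) or dCIS library 1 (0.0952) or 3 (0.104), and those of Etv1 and Sbno1 in a fit of the 8 libraries alone. Il1b, Nlrp3, Tnf and Abca1 had log2 fold changes of -0.28, -0.21, -0.21 and 0.02 (SE 0.442, 0.164, 0.197 and 0.274, adjusted p 1 each).

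By gene list, all 23 cell cycle genes had a positive log2 fold change in untreated dCIS against WT (median 0.57, camera adjusted p 4.93e-27; 0.215 with an estimated correlation). edgeR called 0 of them, with 15 at an unadjusted p under 0.05 and 0 called by DESeq2. All 19 genes of cholesterol synthesis had a negative one (median -0.25, adjusted p 1.27e-08; 0.84 with an estimated correlation). Mitochondrially encoded genes had a median of -0.25 (adjusted p 0.0207), MHC class I presentation 0.12 (adjusted p 0.0231), each at 0.86 with an estimated correlation, and the 4 sex genes 0.22 (adjusted p 0.0231; 0.367 with an estimated correlation; 2 called adjusted over the list alone). The mean log2 CPM of the cell cycle genes was 4.98 ± 0.274 in dCIS and 4.38 ± 0.472 in WT, a difference with an exact 2-sided permutation p of 0.0857. In 1 joint test that exchanged libraries only within numbers 1 and 2 and within 3 and 4, the exact p was 0.0556, the smallest it allows. The numbers were not found to pair dCIS with WT libraries. With the replicate number as a block the list also passed with an estimated correlation (camera adjusted p 0.0101) and by fry (0.00278). In the whole comparison 8 genes were called, 1 higher and 7 lower. With RLE scaling 3 and 7 were called. Without WT library 3, WT library 4 or dCIS library 1 the number was 5, with no filter 80, with the replicate number as a block 34, with DESeq2 15 and without dCIS LPS libraries 3 and 4 it was 16.

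**Figure D5:**
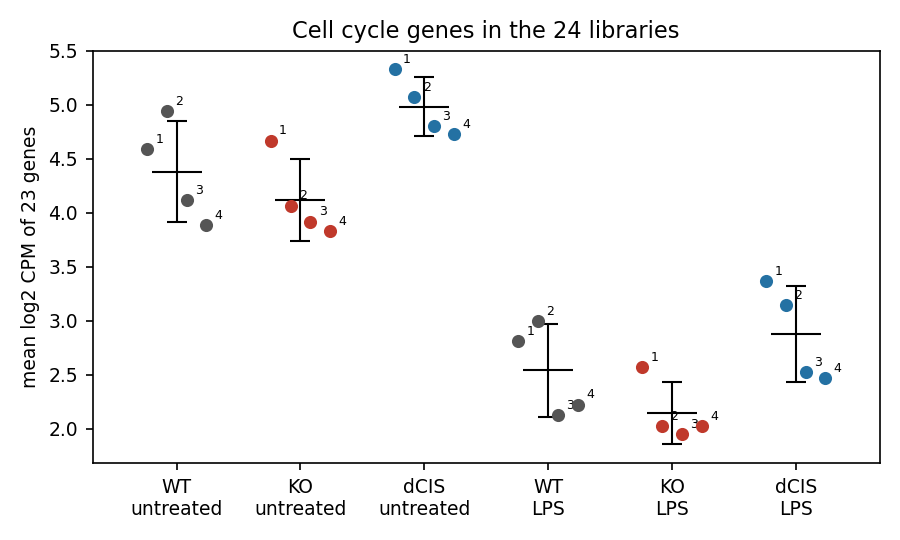
Mean log2 CPM of the 23 cell cycle genes (vertical axis) in each of the 24 libraries by genotype and treatment; numbers mark the replicate, lines the mean and error bars 1 SD of 4 libraries. LPS libraries lie below untreated ones in each genotype, and untreated dCIS has the highest mean.

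After LPS, dCIS macrophages had more RNA of Nr1h3, which encodes the cholesterol-sensing nuclear receptor LXR alpha, at 143 ± 29.7 against 60.3 ± 8.46 CPM in WT (log2 1.25, SE 0.199, adjusted p 0.00281). Mier3 was at 147 ± 22.9 against 66.0 ± 3.83 CPM (log2 1.15, SE 0.103, adjusted p 4.1e-07) and Gpr137b, a lysosomal membrane protein, at 69.0 ± 19.9 against 35.2 ± 4.91 CPM (log2 0.97, SE 0.151, adjusted p 0.0022). Slc7a2, a transporter of cationic amino acids, was at 125 ± 20.7 against 239 ± 48 CPM (log2 -0.94, SE 0.144, adjusted p 0.00209). Il1b was at 635 ± 224 against 921 ± 335 CPM (log2 -0.54, SE 0.32, adjusted p 0.496) and Nlrp3 at 662 ± 106 against 632 ± 116 CPM (log2 0.07, SE 0.161, adjusted p 0.902). Il6 was at 376 ± 74.1 against 601 ± 175 CPM (log2 -0.68, SE 0.221, adjusted p 0.18). As lists, inflammatory cytokines and chemokines had a median of -0.26 and cholesterol synthesis of -0.22 (camera adjusted p 0.0425 each), cell cycle 0.40 and the MEF2 factors and class IIa HDAC-linked genes 0.19 (0.0337 each; 2 MEF2-linked genes called adjusted over the list alone). All 4 were at 0.866 with an estimated correlation.

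Of the 38 genes called in dCIS against WT after LPS, 17 were higher and 21 lower. In dCIS libraries 3 and 4, 610 and 1087 tested genes had no counts, against at most 207 in any other library. Without both of them, a setting chosen after seeing the data, 6 genes were called, 5 of them among the 38. Nr1h3, Gpr137b and Mier3 kept their calls and Slc7a2 did not (log2 -0.82, adjusted p 0.0887), nor did the cytokine and cholesterol synthesis lists (adjusted p 0.353 and 0.603). The number was 16 without WT library 2, 18 without WT library 3, 195 without dCIS library 1 and 18 without dCIS library 3. It was 277 with no filter, 91 with the block, 12 in a fit of the 8 libraries alone and 224 with DESeq2.

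KO and dCIS were compared directly to ask whether losing Hdac9 differs from losing the element. Untreated KO had less RNA of proliferation genes. Birc5, which encodes survivin, was at 9.43 ± 2.22 against 30.1 ± 8.29 CPM in dCIS (log2 -1.68, SE 0.31, adjusted p 0.00162). Stmn1, a regulator of microtubules, was at 20.0 ± 4.36 against 60.1 ± 17.3 CPM, and the kinetochore gene Spc24 at 1.86 ± 0.39 against 5.22 ± 1.45 CPM. Of 23 cell cycle genes 16 fell, 22 adjusted over the list alone (median -0.85, camera adjusted p 1.3e-12; 0.807 with an estimated correlation). Nr1h3 was at 27.3 ± 6.55 against 63.5 ± 18.7 CPM (log2 -1.22, SE 0.2, adjusted p 0.000597), while B3gnt7, a glycosyltransferase gene, was at 5.65 ± 1.14 against 0.608 ± 0.0683 CPM. Of 28 genes of the type I interferon response 9 rose in KO, 10 adjusted over the list alone (median 0.27, adjusted p 0.0124; 0.807 with an estimated correlation). Of 11 mitochondrially encoded genes 6 rose (median 0.64, adjusted p 0.00826; 0.807 with an estimated correlation), with mt-Nd5, a subunit of complex I, at 1959 ± 312 against 859 ± 362 CPM. The calls of mt-Cytb and mt-Nd1 were lost without dCIS library 3 (adjusted p 0.0588 and 0.0556), in which mitochondrial genes took 0.705% of counts against at least 1.07% in each of the other 11 untreated libraries. By fry the mitochondrial and interferon lists did not pass (0.0656 and 0.202). In MHC class I presentation 4 fell and 1 rose, 6 and 1 adjusted over the list alone (median -0.29, adjusted p 0.0327; 0.807 with an estimated correlation). H2-K1, Psmb8 and Psmb10 lost their calls without dCIS library 3 (0.0752, 0.0667 and 0.131) and in a fit of the 8 libraries alone (0.0655, 0.0655 and 0.0711), H2-K1 also without KO library 1 (0.0713) or 3 (0.078), and Psmb10 without KO library 1 (0.0612). The class I list did not pass by fry (0.122) or without dCIS LPS libraries 3 and 4 (0.0514).

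In the inflammasome and IL-1 family 4 of 20 genes rose in untreated KO against dCIS (adjusted p 0.334), namely Naip2, Naip6, Nlrc4 and P2rx7. The call of Naip6 was lost without dCIS library 3 (adjusted p 0.0698), that of Nlrc4 without dCIS library 1 (0.108) or 3 (0.11) or KO library 2 (0.104) or 3 (0.0559), and that of P2rx7 without dCIS library 1 (0.0629), 3 (0.141) or 4 (0.0733) or KO library 2 (0.136). In a fit of the 8 libraries alone Nlrc4 and P2rx7 lost their calls as well (0.0551 and 0.111). Il1b and Nlrp3 had log2 fold changes of 0.29 and 0.20 (adjusted p 0.681 and 0.397). edgeR called 3147 of 14757 tested genes, 1782 higher and 1365 lower in KO, a share close to that of the inflammasome list. It called 1198 without dCIS library 3 and 1317 in a fit of the 8 libraries alone.

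After LPS, KO differed from dCIS in genes that also set it apart from WT, with Odc1 at 38.2 ± 6.4 against 119 ± 11.3 CPM (log2 -1.64, SE 0.159, adjusted p 1.96e-07) and Cd200 at 5.69 ± 1.83 against 22.7 ± 4.44 CPM. Ccdc39 was at 18.5 ± 1.02 against 1.04 ± 0.494 CPM and Steap3 at 39.0 ± 7.35 against 8.80 ± 1.56 CPM. Rnf144a was at 0.51 ± 0.276 against 5.47 ± 1.4 CPM (log2 -3.43, SE 0.345, adjusted p 3.49e-07) and Nr1h3 at 52.9 ± 10.4 against 143 ± 29.7 CPM (log2 -1.44, SE 0.2, adjusted p 9.42e-05). Of 23 cell cycle genes 4 fell, 13 adjusted over the list alone (median -0.83, camera adjusted p 7.78e-06; 0.943 with an estimated correlation; 0.516 by fry). These 4 calls depended on single libraries. That of Birc5 was lost without dCIS library 1 (0.0645) or 4 (0.0618) or KO library 1 (0.0575), 2 (0.052), 3 (0.0778) or 4 (0.0918). That of Ccna2 was lost without dCIS library 4 (0.0726) or KO library 1 (0.0645), 2 (0.0653), 3 (0.0888) or 4 (0.0682), and that of Top2a without dCIS library 1 (0.0618) or 4 (0.0538) or KO library 2 (0.0586), 3 (0.108) or 4 (0.099). Mcm7 lost it without dCIS library 1 (0.0544), 3 (0.0994) or 4 (0.139) or KO library 1 (0.0889), 2 (0.115), 3 (0.139) or 4 (0.063). Without dCIS LPS libraries 3 and 4 all 4 lost it (0.0673, 0.11, 0.0578 and 0.352). Il1b was at 1059 ± 115 against 635 ± 224 CPM (log2 0.74, SE 0.321, adjusted p 0.197) and Il6 at 610 ± 84 against 376 ± 74.1 CPM (log2 0.70, SE 0.221, adjusted p 0.0909). edgeR called 322 genes, 199 higher and 123 lower in KO. The number was 62 without dCIS LPS libraries 3 and 4, with 54 of them among the 322, 850 with no filter, 751 with the block, 82 in a fit of the 8 libraries alone and 675 with DESeq2. Without single libraries it was 150 (KO 1), 149 (KO 3), 139 (KO 4), 1446 (dCIS 2), 122 (dCIS 3) and 155 (dCIS 4).

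Whether KO and dCIS changed the same genes against WT was asked with the shared WT libraries in mind. Untreated, edgeR called 0 genes in the same direction in both and DESeq2 3. At an unadjusted p under 0.05 there were 48, against 69.6 for independent results. Across genes the log2 fold changes had r = 0.0495 and a covariance of 0.00665, against a mean r of 0.502 and a mean covariance of 0.044 in 50 simulations that drew all 12 libraries from the WT means, so both lay below these means (difference of covariances -0.0373). With WT libraries split between the comparisons the mean covariance was -0.0276. After LPS, 5 genes were higher in both and 2 lower in both, against 0.393 and 0.0911 for independent calls, which ignores the shared WT libraries. With these split between the comparisons the mean numbers were 0.167 and 0.667, against 0.0176 and 0.0217 for independent calls. The split fits had fewer WT libraries per comparison, and the numbers of genes they called in KO varied widely. In KO, 1 of the 6 splits called 614 genes higher and 300 lower, more than the 341 and 64 of the main fit. The other splits called 14 to 33 higher and 13 to 23 lower. Over the 6 splits the means were 120 higher and 65.7 lower in KO, and 3 higher and 4.83 lower in dCIS. Across genes after LPS, r was 0.346 and the covariance 0.0784. The simulations gave means of 0.494 and 0.0594 (highest covariance 0.0645, difference of covariances 0.019), and the split WT libraries 0.0806 and 0.0226. At both treatments the simulations drew each gene and each library independently. Genes that move together in real libraries would widen the spread of the covariances. A value above the highest simulated one therefore does not show a shared effect.

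Genes near Hdac9 were counted for a touch of either change on the neighbourhood. Of 77 genes annotated within 2 Mb of Hdac9, 16 were tested. Atxn7l1 was higher in KO than in WT, at 38.9 ± 2.43 against 27.5 ± 0.599 CPM untreated (log2 0.50, SE 0.12, adjusted p 0.0201) and at 179 ± 13.6 against 129 ± 17.1 CPM after LPS (log2 0.47, SE 0.117, adjusted p 0.0325). The untreated call was lost without WT library 2 (adjusted p 0.0756) or 3 (0.0708), and that after LPS without WT library 1 (0.0656), 2 (0.0659) or 3 (0.187) or KO library 1 (0.134), 2 (0.0559) or 3 (0.0666). In dCIS against WT edgeR and DESeq2 called 0 of the 16 at either treatment, with 0 at an unadjusted p under 0.05 untreated and 3 after LPS. Among all tested genes 3.61% and 13.1% were at such a p. Atxn7l1 had log2 fold changes of 0.05 and 0.11 (adjusted p 1 and 0.721), and Pik3cg, a kinase of leukocyte signalling, -0.19 and 0.24 (adjusted p 1 and 0.541). Pik3cg was at 117 ± 17.5 CPM in untreated KO and 78.6 ± 22.3 CPM in untreated dCIS, with overlapping libraries (log2 0.57, SE 0.154, adjusted p 0.0117; 0.06 without dCIS library 3 and 0.0731 in a fit of the 8 libraries alone). In a window of 5 Mb, 29 genes were tested. In KO against WT 4 of them were called untreated, 3 higher and 1 lower, and 2 after LPS, 1 higher and 1 lower, while in dCIS against WT Etv1 was lower untreated.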

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

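The tests of neighbouring genes among the KO and dCIS calls, of the chromosome of the genes with a different LPS response in KO, and of the totals of dCIS LPS libraries 3 and 4 were chosen only after the result was seen. So were the fits without dCIS LPS libraries 3 and 4 or 1 and 2, while the test of read sharing was written before.

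Genes with a changed RNA level in KO lay next to each other on the chromosomes more often than random genes. Of 50 genes changed at least 2-fold in KO against WT in the same direction at both treatments, 47 had a position in GRCm38, and they made 41 loci, of which 15 had another changed locus within 20 tested genes; the 95th percentile of 10000 random sets was 10. This fits chromosome segments of another mouse strain that stayed in the KO line, and away from the chromosome of Hdac9 the number was 13 against a 95th percentile of 8. On that chromosome lay 6 of the 47 genes (12.8%), Odc1 and Acp1 among them, against 3.54% of tested genes. All 3 genes with a different LPS response in KO, Nol10, Adi1 and Rnf144a, lie on the chromosome of Hdac9, as a segment of another strain there would give. The hypergeometric p was 4.41e-05, but it treats the 3 genes as independent and restates the observation that prompted the test. It adds no support of its own. Reads shared by overlapping or adjacent genes are argued against, since the 15 were counted after changed genes within 2 tested genes of each other had been merged into 1 locus. Paralogs further apart, but within 20 tested genes, were not merged, so reads shared among them were not tested. The 43 dCIS genes, Hpn among them, gave 11 such loci against a 95th percentile of 9. They include the mitochondrial genes mt-Ti, mt-Tm and mt-Ta, which cannot lie in a segment of a nuclear chromosome, and the count without these was not run. As a control, 50 random genes raised by LPS in WT gave 10 such loci, against a mean of 5.62 and a 95th percentile of 11 in random sets. An effect of Hdac9 or of the element on groups of neighbouring genes was not tested and stays open. The changed genes of KO and dCIS may therefore reflect the mouse lines and not the targeted change.

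The 38 calls of dCIS against WT after LPS involve libraries 3 and 4, in which fewer genes were detected. Whether few distinct molecules in these libraries are part of the cause is not decided. Without them a median of 0.852 of the log2 fold change was kept (quartiles 0.687 and 0.991; 38 of 38 genes in the same direction) and 6 genes were called at a median SE of 0.212 against 0.206, while without libraries 1 and 2 the median share was 1.14 (quartiles 1.01 and 1.33) and 1067 genes were called. Lower depth is argued against, since 0 of the totals of these libraries, 16651501 and 14813435, lay below the lowest other total of 14636058. An effect of the element stays open, as does that of the mouse line.

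The cell cycle list stood higher in untreated dCIS than in WT, with a mean score of 4.98 ± 0.274 against 4.38 ± 0.472. Numbers 1 and 2 scored above 3 and 4 in WT and dCIS at both treatments. The dCIS library lay above the WT library of its number in 4 of 4 cases untreated and after LPS. A joint test that exchanged libraries only within numbers 1 and 2 and within 3 and 4 gave an exact p of 0.0556 untreated and 0.0556 after LPS. That is the smallest this test allows, and the division follows the scores. Between dCIS and WT, only 2 of 4 pairs untreated and 1 of 4 after LPS exceeded the correlation limit. Matching or blocking these libraries by number is therefore not backed by the pairing check. Chance differences in proliferation between cultures remain open, since the exact 2-sided permutation p of the untreated score, which ignores the numbers, was 0.0857. With the replicate number as a block the list passed with an estimated correlation too (camera adjusted p 0.0101; 0.00278 by fry), which without the block it did not (0.215 and 0.338). An effect of the element on proliferation was not tested apart from these and stays open.

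Regrouping the 8 libraries of a comparison asks whether chance can give as many calls. There are 35 splits of 4 and 4. For a difference of LPS responses, the untreated and LPS libraries of a number were moved together. In each comparison except the difference of dCIS, 1 of 35 splits, the real one, gave as many. That is the smallest share 35 splits allow, and it was not adjusted over the comparisons. Splits that mix the groups also carry the real difference in their spread and so call few genes. A chance division of the libraries is therefore not excluded by these counts. The real number and the highest of the other splits were 9055 and 0 for LPS in WT, 9085 and 4 for LPS in KO, and 9547 and 2659 for LPS in dCIS. They were 1079 and 131 for KO against WT untreated, 8 and 0 for dCIS against WT untreated, 405 and 0 for KO against WT after LPS and 38 and 0 for dCIS against WT after LPS. They were 3147 and 1642 for KO against dCIS untreated, 322 and 3 for KO against dCIS after LPS, and 3 and 0 for the difference of the LPS response of KO. For that of dCIS all 35 of 35 splits gave 0 genes by edgeR, so that count holds no information on chance. Other splits that call many genes point to a structure of the libraries: the 2659 came from untreated dCIS libraries 1, 3 and 4 with LPS library 3 on one side, and the 1642 from KO 1, 2 and 3 with dCIS 2. Where the numbers pair the libraries, 8 splits part all 4 pairs, too few for a share under 0.05. The real numbers there were 9055, 9085 and 3147, and the highest other of these splits was 0 for LPS in WT and in KO and 359 for KO against dCIS untreated. With the replicate number as a block that comparison called 3911 genes.

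In 32 of 452 groups of 4 libraries (7.08%; chance gives about 1 in 20), 1 library stood so far out that its gap to the nearest, divided by the range of the group, passed the 95% limit of Dixon's test. Among untreated KO libraries, number 2 was highest for Nos2 (ratio 0.98585; 3.09 against 0.235 CPM), Engase (0.87976; 19.8 against 8.17), Adam19 (0.94157; 14.2 against 4.7), Arl4c (0.84896; 65.8 against 36.6), Abca1 (0.86377; 475 against 254), Abcg1 (0.87427; 154 against 73.5) and P2rx7 (0.95327; 115 against 73.6 CPM). Number 1 was highest there for Clspn (0.86958; 15.3 against 8.36 CPM), Spc25 (0.92182; 8.43 against 4.88), Mcm7 (0.88777; 32.3 against 22.3) and Tpx2 (0.83858; 27.5 against 17.5), number 3 for BC002163 (0.82903; 7.32 against 6.27), and number 4 was lowest for Naip6 (0.83141; 14.6 against 18.8 CPM). In KO after LPS, library 2 was highest for Tnf (0.90702; 2370 against 1730 CPM) and Abcg1 (0.85106; 248 against 154 CPM), and library 1 for the cell cycle score (0.87521; 2.57 against 2.02).

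In untreated WT, library 1 was highest for Nlrp3 (0.93273; 81.8 against 54.1 CPM) and Tnf (0.99362; 169 against 101 CPM), library 4 for Ddx58 (0.83123; 74.1 against 59 CPM), and library 2 was lowest for Uty (0.91852; 10 against 12.6 CPM). In WT after LPS, library 2 was highest for Hdac9 (0.84714; 16.5 against 11.4 CPM), Cxcl9 (0.85924; 304 against 238 CPM) and Rasgrp3 (1; 0.155 against 0 CPM), and library 1 for Ung (1; 0.245 against 0 CPM), Cnr2 (0.98094; 0.245 against 0.0808 CPM) and Nol10 (0.83908; 37.9 against 35.8 CPM). In dCIS after LPS, library 4 had the lowest total count (0.86506; 14800000 against 16400000) and was lowest for Maoa (0.93716; 1.64 against 3.37 CPM). Library 3 there was lowest for Slc7a2 (0.84236; 94.4 against 132 CPM) and Ccna2 (0.87662; 2.34 against 3.84 CPM), library 1 highest for Ung (1; 0.0811 against 0 CPM) and library 2 for Rasgrp3 (1; 0.164 against 0 CPM).

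The response to LPS differed between KO and WT, by the test of the difference itself, for Adi1 (1.468 on the log2 scale), Rnf144a (-3.259) and Nol10 (1.315) and, with camera at the preset correlation, for the type I interferon response (median -0.196; adjusted p 0.977 with an estimated correlation). The call of Adi1 was lost without untreated WT 4 (adjusted p 0.0546), untreated KO 1 (0.0604) or 4 (0.0579), WT LPS 1 (0.0791), 2 (0.0688) or 3 (0.0882), or KO LPS 2 (0.0607), or in a fit of the compared groups alone (0.0869). Between dCIS and WT the lists of MHC class I presentation (median -0.269) and of MEF2 factors and class IIa HDAC-linked genes (median 0.296) differed with camera, each at an adjusted p of 0.999 with an estimated correlation and of 1 by fry. The second was lost without dCIS LPS libraries 3 and 4 (0.0537).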

How the results depend on the processing

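The fits without dCIS LPS libraries 3 and 4 or 1 and 2 together, and without both KO libraries 2, were chosen only after the result was seen. Of 213 named gene results that passed the test, 145 kept their direction and call under every alternative, 68 lost the call under at least 1 and 0 changed direction. Of 55 that did not pass, 9 passed under at least 1 alternative and 24 changed sign under at least 1. The counts of LPS in WT, KO and dCIS stayed within 1.5 times under every alternative run, and without 1 library lay at 8629 to 8717, 8675 to 8830 and 9206 to 9540. The fold of Hdac9 in KO against WT kept its direction and call throughout. Precision is limited by 4 libraries per group. In dCIS after LPS, libraries 3 and 4 had 17628 and 15997 detected genes, but whether this limits precision was not settled. The median SE of the 38 calls against WT was 0.206 with these libraries and 0.212 without them. The cause of the changes that follow was not tested, except that fits without libraries hold fewer samples and a filter changes the genes tested.

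Leaving out 1 library moved the number of called genes to 90 to 951 for KO against WT untreated, 5 to 9 for dCIS against WT untreated, 68 to 455 for KO against WT after LPS. They were 16 to 195 for dCIS against WT after LPS, 1198 to 4488 for KO against dCIS untreated, 122 to 1446 for KO against dCIS after LPS and 0 to 3 for the difference of the LPS response of dCIS. The log2 fold change of Hdac9 with LPS moved to -0.042 to 0.206 in WT and -0.33 to 0.056 in dCIS. With DESeq2 the numbers were 2164, 15, 1093, 224 and 675 for KO against WT untreated, dCIS against WT untreated, KO against WT after LPS, dCIS against WT after LPS and KO against dCIS after LPS, and 5 and 1 for the LPS response of KO and of dCIS minus WT. With no filter they were 80, 1038, 277 and 850 for dCIS against WT untreated, KO against WT after LPS, dCIS against WT after LPS and KO against dCIS after LPS, and 12 and 35 for the differences of KO and dCIS. Hdac9 with LPS in WT was at -0.029, and its difference for KO, -1.876, passed the test. With the replicate number as a block they were 1973, 34, 1058, 91 and 751 in the order given for DESeq2 and 1 for the difference of dCIS, which was also 1 with the block within each genotype and with the stricter filter. In fits of the compared groups alone they were 2351 for KO against WT untreated, 1995 for KO against WT after LPS, 12 for dCIS against WT after LPS, 1317 for KO against dCIS untreated and 82 for KO against dCIS after LPS.

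Without dCIS LPS libraries 3 and 4 the numbers were 1770, 16, 872, 6 and 62 in the order given for DESeq2 and 1 for the difference of dCIS. Hdac9 with LPS in dCIS was at 0.272 and its difference from WT at 0.139. Camera passed 2 lists for dCIS against WT after LPS, 2 for KO against dCIS after LPS and 1 for the difference of dCIS. Without dCIS LPS libraries 1 and 2, dCIS against WT after LPS called 1067 genes. Without both KO libraries 2, 1000 genes were called in KO against WT untreated and 322 after LPS, and each count run lay within 1.5 times.

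Called neighbours of Hdac9 in KO against WT untreated were 2 with RLE scaling, 2 with no filter, 2 with the block and 3 in the fit of the compared groups; the block gave 5 for KO against dCIS untreated and 1 after LPS. In a window of 5 Mb they were 4 for KO against WT untreated, 1 for dCIS against WT untreated, 2 for KO against WT after LPS, and 6 and 2 for KO against dCIS untreated and after LPS. With the estimated correlation camera called 0 lists in each of the 10 comparisons in which the preset one called any. By fry 20 passed for LPS in KO, 1 for KO against WT untreated, 0 for dCIS against WT untreated, 0 for dCIS against WT after LPS, 1 for KO against dCIS untreated, 0 after LPS, and 0 for the differences of KO and of dCIS. With the block camera called 1 list for KO against WT untreated and 2 each for KO against WT after LPS, KO against dCIS after LPS and the difference of KO. With the WT libraries split, the covariance of the KO and dCIS effects was -0.0276 untreated and 0.0226 after LPS.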

Other observations

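All of the tests in this part on single libraries and numbers use genes chosen after their values were seen; the test on shared numbers was written before its result was seen.

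KO macrophages of number 2 stood apart from the other KO libraries in the same genes before and after LPS. Selenop, which encodes a secreted selenoprotein, was at 3649 CPM in untreated KO library 2 against 624 to 866 CPM in the other 3, and at 2592 against 650 to 926 CPM after LPS. Gas6, a ligand of receptors for dead cells, was at 561 against 160 to 255 CPM untreated and 281 against 75.7 to 118 CPM after LPS, and Pltp, a phospholipid transfer protein, at 1225 against 398 to 563 CPM and 1302 against 458 to 650 CPM. Pgk1, an enzyme of glycolysis, was at 95.1 against 192 to 256 CPM and 142 against at least 299 CPM, and the lactate transporter gene Slc16a3 at 24.2 against 60.7 to 86.7 CPM and 33.2 against 69.5 to 91.7 CPM. Of 47 genes that split the 4 KO libraries by at least 2-fold at both treatments, 43 split the numbers alike, 40 with number 2 alone apart, 35 higher and 5 lower; other matchings of the numbers gave 9.26 on average, but 2 of 24 matchings gave as many, since exchanging numbers on the same side leaves a split unchanged. Without both KO libraries 2, 1000 genes were called in KO against WT untreated and 322 after LPS.

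Ifi208, an interferon-inducible gene, was nearly silent in some dCIS libraries. After LPS it was at 5.68 and 6.08 CPM in dCIS libraries 1 and 3 and at 431 and 348 CPM in libraries 2 and 4, against 300 to 417 CPM in the WT and KO libraries. Untreated it was at 0.047 and 0.248 CPM in libraries 1 and 3 and at 3.33 and 4.79 CPM in libraries 2 and 4, against 3.05 to 7.31 CPM. A candidate explanation is that dCIS libraries of the same number come from the same animal and that the animals carry different alleles; 3 genes split the dCIS numbers alike at both treatments, of 21 that split them at all. Of 24 matchings of the numbers 2 gave as many, a share of 0.0833, so this count does not decide. A pair of numbers on the same side of a split can be exchanged without changing the split, so another matching can give as many even if numbers mark animals. Over all tested genes each untreated dCIS library correlated best with the LPS library of its own number, in 4 of 4 cases (r 0.0396 to 0.339), but 2 of the 4 pairs lay under the limit of 0.1, and a shared culture or day would give the same, so the explanation stays open.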
